A study of Mus musculus with 2 samples.

How the data were processed

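Poly(A)-selected RNA from the brain of 1 adult male C57BL/6J mouse, an inbred laboratory strain, was sequenced in 2 libraries. The labels name them technical replicates 1 and 2 of biological replicate 1, with an age of 10 weeks and RNA taken with a kit for lipid-rich tissue. Per the labels, replicate 2 was made later than the publication they name. There was 1 group and no treatment, so the comparison made is between the libraries. Both come from 1 mouse and are labelled technical replicates, so their spread holds no difference between animals. Whether they share 1 RNA extract or 1 piece of tissue is not given in the sources used here.

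For each library the authors deposited a gene table and a transcript table. The expected counts were deposited by the authors as estimates that need not be whole numbers. TPM, a transcript level scaled to the same total in each library, was deposited by the authors per gene and per transcript. FPKM, a fragment level scaled by length and depth, was likewise deposited by the authors. The percent of a gene's expression held by each transcript was deposited by the authors in the transcript tables. Posterior mean versions of the counts, TPM and transcript shares stand beside these, per the file headers. The deposited file listings name mm10 and GENCODE M4. The column names are those RSEM writes, and the quantifier, the aligner and their versions are not given in the sources used here. Strand-separated signal tracks are listed but not used here.

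Of the rows of each gene table, 43346 carried an Ensembl gene identifier, 26248 a number and 97 a spike-in name. The numbered rows held 0 counts in replicate 1 and 1 count in replicate 2, and the spike-in rows held 0 in both, so rows other than genes were left out. Gene symbols, positions and transcript sequences came from GENCODE M21, a later release on the same build (GRCm38), matched by identifier without version. A symbol was found for 42462 genes, and where a symbol had several identifiers the one of highest mean TPM was used. A sequence was found for 97.95% of transcripts, with the same length for 88.21%. A gene's GC content is the mean over its transcripts weighted by mean TPM.

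Depth was 18302506 counts in replicate 1 and 17828479 in replicate 2. A count of 0 allows up to 3 counts, a share of 1.64e-05% of the total in replicate 1 and 1.68e-05% in replicate 2. Intervals (exact Clopper-Pearson, 95%) and these floors cover counting error only. A fold against a library at 0 is a lower bound taken against 3 counts in that library.

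Log2 ratios are log2 of (TPM + 1) in replicate 2 over replicate 1, which understates the change of low genes. Agreement was described over genes with a mean TPM of at least 1. Expected counts were rounded to whole numbers and compared gene by gene with a two-sided exact binomial test, with library sizes scaled by TMM (edgeR 4.0.16 in R 4.3.3), for genes with at least 10 counts in the sum. A gene is called different at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, with 0.5 added to each count for the fold. This test compares these libraries, not conditions. The quasi-likelihood test of edgeR and the test of DESeq2 could not be fitted with 1 library per side, and the differences have no replicate check. Sampling noise was simulated with 20 Poisson draws at the same depths. Smooth trends on GC content and length were fitted by lowess with a fraction of 0.2 (statsmodels 0.14.6). Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

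The 41 gene lists with 390 members, 388 of them measured, were fixed before the data were examined. The 26 cell type or tissue lists cover pan-neuronal genes, glutamatergic, GABAergic, striatal projection, cerebellar, thalamic, hippocampal, olfactory bulb, and monoaminergic and cholinergic neurons, hypothalamic neuropeptides, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, choroid plexus, ependymal cells, meningeal fibroblasts, erythroid cells, blood leukocytes, anterior pituitary, photoreceptors and pineal, liver, skeletal muscle and testis germ cells. The 15 others cover immediate early genes, heat shock, circadian clock, proliferation, adult neurogenesis, ionotropic glutamate receptors, GABA-A receptor subunits, neurodegeneration-linked genes, mitochondrial mRNAs, mitochondrial rRNAs, ribosomal proteins, RNAs mostly without a poly(A) tail, long noncoding RNAs, sex-linked genes and housekeeping genes. Each list's median log2 ratio was placed among 10000 random lists of the same size, each member drawn from the 100 genes nearest to it in mean expression. The named genes were fixed by rule: the 3 members of highest mean TPM of each list and any member called different, the 10 genes of highest mean TPM, the 10 highest and 10 lowest log2 ratios among called genes with a symbol and a mean TPM of at least 1, 28 genes with known isoforms, Nnt, and the sex-linked genes. Other members named in the text are given as values. Leading transcripts were compared in genes with more than 1 expressed transcript and a mean TPM of at least 5.

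The count test was tested on simulated data for this comparison, with 16337 genes in the step. Of 50 genes changed 8-fold, 90.0% were called, of 50 changed 4-fold 92.0%, of 50 changed 2-fold 32.0%, and of 50 changed 1.5-fold 0. The 9 genes missed at 4-fold or 8-fold had at most 15 counts in the sum. All 88 such genes with at least 50 counts were called, and 0 of 16147 unchanged genes were. Of 20 unchanged lists, 1 fell outside the middle 95%, as did 5 of 5 lists raised 2-fold. These simulated ratios held counting noise only, and the ranges of random lists in the data were wider. For astrocytes the range was -0.19 to 2.55 about a median of 0.84, so a list raised 2-fold could lie inside it. A place inside the middle 95% therefore does not exclude a 2-fold shift. With a GC trend laid over the same changes, 45.24% of 16196 unchanged genes were called before the trend was removed and 0.01% after. That trend followed GC content exactly apart from counting noise, so the 0.01% shows only that such a trend can be removed. It gives no rate of false calls for the GC-corrected data. Alternatives tried were other size factors, filters, pseudocounts and units, each library left out, and corrections for length. GC corrections, lists matched on GC, and counts of exon junctions were chosen after seeing the data.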

Results

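The data are poly(A) RNA levels of brain tissue from 1 male mouse in 2 libraries, with 18302506 counts in replicate 1 and 17828479 in replicate 2. A TPM of at least 1 was reached by 11608 genes in replicate 1 and 14780 in replicate 2. The labels state no comparison of conditions, so the question addressed is which brain transcripts the libraries measured alike and which they did not. Each side is 1 library, so no difference has a replicate check, and a mean ± SD is over both libraries of 1 mouse.

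Transcripts of neurons and glia were abundant in both libraries, and their levels differed widely between them. Snap25, a synaptic vesicle fusion protein (ENSMUSG00000027273.9, chromosome 2, 136713453 to 136782428, GRCm38), had a TPM of 3457 in replicate 1 and 2764 in replicate 2 (3110 ± 490, SD, n = 2). The astrocyte glutamate transporter gene Slc1a2 stood at 397 and 346 TPM (371 ± 35.7, SD, n = 2). Mbp, a myelin protein gene (chromosome 18, 82475146 to 82585637), was at 249.9 TPM in replicate 1 and 2734 in replicate 2. Apoe, the lipid carrier of astrocytes (chromosome 7, 19696109 to 19699188), was at 8.51 and 2133 TPM, a ratio of 251 (95% counting interval 208 to 304). Gapdh, the glycolytic enzyme gene often used as a reference (chromosome 6, 125161715 to 125166467), was at 43.4 and 2172 TPM, a ratio of 50.1 (44.6 to 56.5). Its counts were 284 and 28945, and its effective length, which follows the estimated mix of transcripts, was 455.83 bases in replicate 1 and 1229.29 in replicate 2. The intervals do not cover the error of that mix.

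Across 14229 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) was 0.666 and Spearman's rho 0.622. Genes are not independent replicates, so no p is given. The median log2 ratio of replicate 2 over replicate 1 was 0.88, and the median absolute log2 ratio 0.97. A log2 ratio above 0 is thus not by itself high among these genes. Lists of low genes, whose ratios are understated, are to be read against random lists of the same expression instead. The median of those was 0.38 for the liver list, 0.13 for testis germ cells and 0.0 for RNAs mostly without a poly(A) tail. Poisson draws at these depths gave a median absolute log2 ratio of 0.061 and an r of 0.9912. Of these genes, 7018 (49.3%) differed by at least 1 on the log2 scale.

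**Figure D1:**
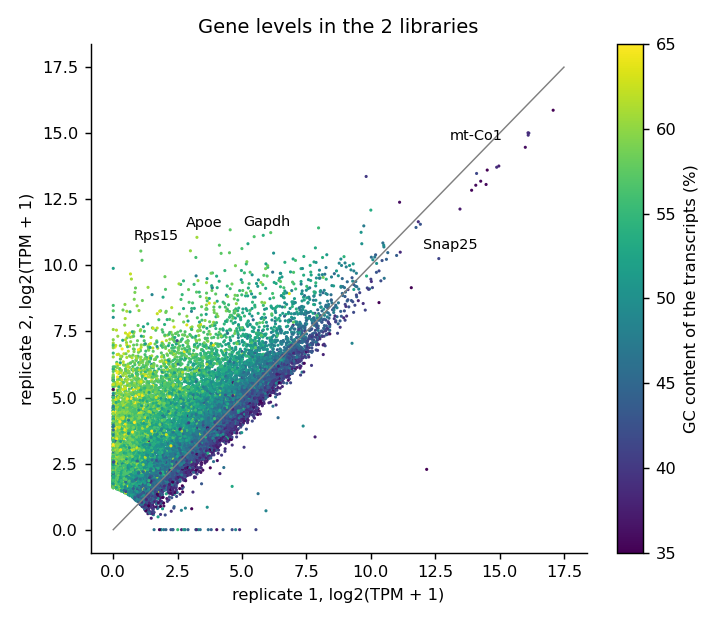
Level of each gene with a mean TPM of at least 1 and a known GC content in replicate 1 (x axis) and replicate 2 (y axis), as log2(TPM + 1), coloured by the GC content of its transcripts. The line marks equal levels, Pearson's r over 14229 genes was 0.666, and Gapdh, Apoe and Rps15 lie far above the line.

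Mitochondrially encoded genes and nuclear copies of them led both libraries. The 10 genes of highest mean TPM were mt-Atp8, mt-Co1, mt-Nd1, mt-Cytb and mt-Nd2, which encode subunits of the respiratory chain and ATP synthase, and Gm28437, Gm28661, Gm10925, Gm10222 and Gm28438 in a nuclear copy of mitochondrial DNA on chromosome 1. The TPM of mt-Co1 was 72070 in replicate 1 and 32830 in replicate 2, and that of mt-Nd1 32110 and 13850. Mitochondrial genes and these copies together held 63.2% of TPM in replicate 1 and 29.1% in replicate 2. Of expected counts, which are not divided by length, they held 29.8% and 10.4%. The 100 most abundant genes held 70.0% of TPM in replicate 1 and 40.1% in replicate 2. Reads of the copies and of the mitochondrial genes cannot be assigned with certainty, and mt-Atp8 is short and overlaps mt-Atp6, so their separate levels are uncertain. Of 13 mitochondrial mRNAs 12 were called lower in replicate 2, as were both mitochondrial rRNAs, whose list median log2 ratios were -1.21 and -1.06.

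Beyond counting error, 9502 of 16320 tested genes differed between the libraries, 5624 higher and 3878 lower in replicate 2 (exact binomial test on rounded expected counts, TMM sizes). With library totals in place of TMM the ratios moved by 0.61 on the log2 scale, and 84.7% of called genes were higher, against 59.2% with TMM. The median log2 count ratio of tested genes was 0.09 with TMM and 0.70 with totals. Of the genes called lower, 195 had a higher TPM in replicate 2. TPM is not scaled by TMM and is also divided by the effective length in each library. Of the genes called higher, 1 had a lower TPM in replicate 2. A lower call can thus stand beside near-equal TPM, and a TPM ratio above 2 can go without a call. Cldn11, at 166.1 and 160.9 TPM, was called lower, and App, at 406 and 884 TPM, was not called. What accounts for the 195 genes was not tested. With the length trend removed 47.6% of called genes were higher. Genes with the highest log2 ratios included Rps15 and Rpl36 of the ribosome, Mif, a cytokine, Mt3, a metallothionein of brain, Uqcr11 of the respiratory chain, Rpl8, and the globin Hba-a1. Rps15 had 5 counts in replicate 1 and 5068 in replicate 2, with 1.1 and 1489 TPM. Mt3 had 3 and 3108 counts, a TPM ratio of 1380 (counting interval 473 to 6710). Hba-a1 had 0 and 1707 counts, at least 615-fold higher in replicate 2, though its reads are shared with Hba-a2. Snurf, which overlaps another gene, and Gm10076, also among the highest, had 0 counts in replicate 1 and are uncertain for overlap or shared reads. The 10 lowest log2 ratios, 7 of them of genes annotated as pseudogenes, were those of Gm28439, Gm8797, Gm13502, Gm28037, Gm15899, Gm6829, Gm14440, Rpl38-ps2, Gm14388 and BC002163. Gm28439, in the nuclear mitochondrial copy, had 45875 counts in replicate 1 and 29 in replicate 2, and such genes share reads with near-identical copies.

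The levels in the libraries differed along the GC content of the transcripts. Genes with 35 to 40% GC had a median TPM of 21.0 in replicate 1 and 12.4 in replicate 2, and genes with 55 to 60% GC had 1.0 and 20.8. The median log2 ratio went from -0.72 in the first of these classes to 0.41 at 45 to 50% GC and 3.03 at 55 to 60%. Of 2758 genes with 55 to 60% GC, 2529 were called higher in replicate 2 and 11 lower. Among 2699 genes with 40 to 45% GC, 4 were called higher and 2098 lower. Across 14188 genes Spearman's rho of the log2 ratio and GC content was 0.89, and with gene length it was -0.24. Within replicate 1 the rho of TPM and GC content was -0.58, and within replicate 2 it was 0.1. At a TPM of at least 1, 3411 genes were found in replicate 2 alone and 239 in replicate 1 alone, with a median GC content of 56.2% and 42.3%.

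**Figure D2:**
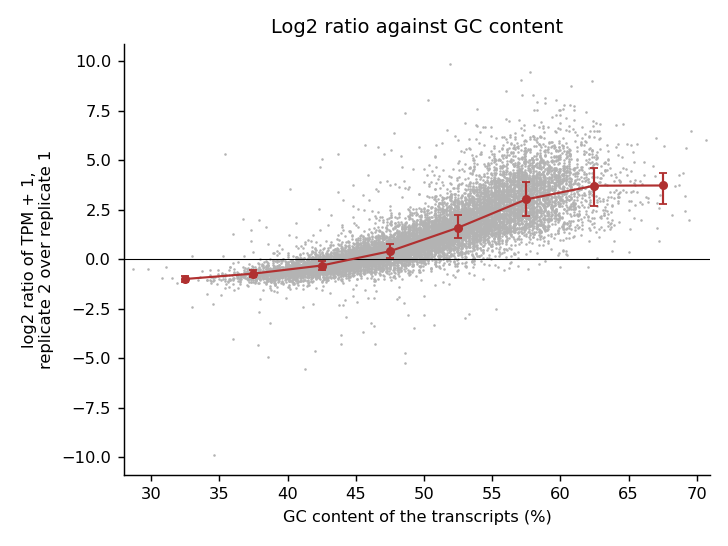
Log2 ratio of TPM + 1, replicate 2 over replicate 1, against the GC content of each gene's transcripts in percent. Grey points are genes with a mean TPM of at least 1, and red points with bars are the median and the middle 50 percent range of genes in 5% classes, from -0.99 at 30 to 35% GC to 3.73 at 65 to 70%.

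Neuronal genes of various classes were expressed in both libraries, and directions below are those of the count test with TMM sizes. Of 12 pan-neuronal genes 5 were called higher and 2 lower in replicate 2, with a list median log2 ratio of 1.33. The microtubule protein gene Map2 was at 607 and 406 TPM, and Syt1, a calcium sensor of vesicle release, at 503 and 570. Of 10 genes of glutamatergic neurons 3 were higher and 4 lower (median 0.30), and with library totals 4 and 0. Slc17a7, the vesicular glutamate transporter, was at 25.5 and 466 TPM, and Nrgn at 35.5 and 1125. Of 11 GABAergic genes 4 were higher and 2 lower (median 1.48), with Sst at 97.6 and 568 TPM and Gad1, a GABA-synthesising enzyme, at 179 and 259. Striatal projection neuron genes had 5 of 10 higher and 1 lower (median 1.78), including Ppp1r1b at 11.1 and 322 TPM and Penk at 44.1 and 359. With library totals 0 genes of the pan-neuronal, GABAergic and striatal lists were lower, and 6, 6 and 5 were higher.

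Cerebellar genes were the regional markers with the most lower calls. Of 10 cerebellar genes 0 were higher and 5 lower (median 0.03). Calb1 was at 96.1 and 52.5 TPM, of list sums of 140.0 and 105.7, while Pcp2, specific to Purkinje cells, had 0 and 1 counts. The granule cell gene Gabra6 had 11 and 2 counts, a TPM ratio of 0.216 (counting interval 0.0233 to 0.991). Zic1 was called lower with a TPM of 12.9 in replicate 1 and 15.7 in replicate 2. With library totals 2 cerebellar genes were lower and 1 higher. Thalamic genes had 3 of 7 higher and 1 lower (median 1.06), with Prkcd at 7.97 and 52.7 TPM. Hippocampal genes had 4 of 8 higher and 2 lower (median 0.88), with Wfs1 at 4.62 and 37.3 TPM, and olfactory bulb genes had 1 of 5 higher (median 0.21). Among 11 hypothalamic neuropeptides 3 were higher and 1 lower (median 0.30). Avp and Oxt had 0 counts in both libraries. Monoaminergic and cholinergic genes had 3 of 11 higher and 3 lower (median 0.34), with Th, the first enzyme of dopamine synthesis, at 1 and 120 counts (TPM ratio 29.3, counting interval 5.16 to 1170) and Tph2, of serotonin synthesis, at 12.1 and 9.83 TPM. With library totals 0 genes of the thalamic, hippocampal and hypothalamic lists were lower, and 5 of the monoaminergic and cholinergic genes were higher and 1 lower.

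Genes of glia and vessels were called higher or lower within most lists with TMM sizes, and most lower calls ended with library totals. Of 12 astrocyte genes 3 were higher and 3 lower (median 0.83), with Aldoc at 199 and 1022 TPM. Of 13 oligodendrocyte genes 5 were higher and 4 lower (median 0.26), and of 9 precursor genes 4 were higher and 1 lower (median 1.22), with Olig1 at 11.5 and 75.5 TPM. Of 12 microglial genes 6 were higher and 2 lower (median 2.23). Complement genes C1qa and C1qb were at 1.95 and 70.5 TPM and at 0.69 and 81.4 TPM, whereas P2ry12 was at 47.71 and 34.03. Endothelial genes had 3 of 10 higher and 1 lower (median 0.69), and mural cell genes 8 of 10 higher and 1 lower (median 1.69), with Rgs5 at 88.0 and 61.4 TPM and Vtn at 4.92 and 59.8. With library totals 4 astrocyte, 6 microglial, 5 precursor and 8 mural cell genes were higher and 0 lower, while 5 oligodendrocyte genes were higher and 2 lower and 4 endothelial genes higher and 1 lower.

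**Figure D3:**
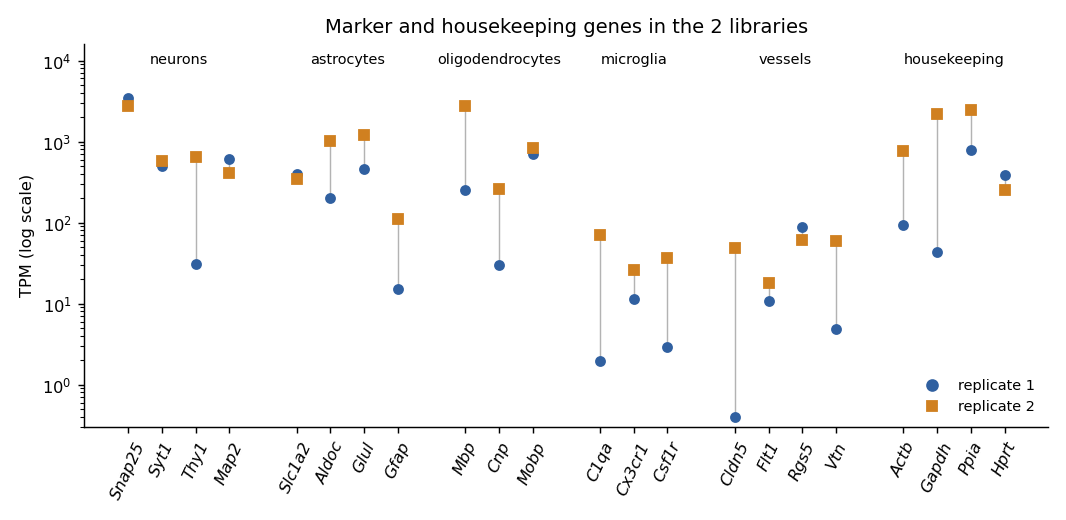
TPM on a log scale of marker and housekeeping genes in replicate 1 (circles) and replicate 2 (squares), 1 value per library, joined by a line for each gene. Gapdh was at 43.4 TPM in replicate 1 and 2172 in replicate 2.

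Ttr, the thyroid hormone carrier of choroid plexus, was at 71.99 and 855.8 TPM, and 4 of 12 choroid plexus genes were higher and 2 lower (median 0.41). Ependymal genes had 7 of 8 higher and 0 lower (median 2.24), with Rarres2 at 0.53 and 21.4 TPM. Meningeal fibroblast genes had 2 of 9 higher and 2 lower (median 0.82). All 5 tested erythroid genes were higher (median 3.75), including Hbb-bs at 46.3 and 635 TPM. Of 9 blood leukocyte genes 0 were higher and 2 lower (median 0.00). The 7 anterior pituitary genes had 0 counts except Prl, with 0 and 1. Photoreceptor and pineal genes had 1 of 7 higher (median 0.12), liver genes 4 of 8 (median 0.78), skeletal muscle genes 2 of 8 (median 0.76) and testis germ cell genes 0 of 6 (median 0.58), with Alb, serum albumin, at 3 and 105 counts (TPM ratio 47.5, counting interval 15.8 to 234). With library totals 1 gene was lower in each of the choroid plexus, meningeal and leukocyte lists, and 6 liver and 4 muscle genes were higher.

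Among the functional lists, ribosomal protein genes stood highest. Of 15 members 12 were higher in replicate 2 and 0 lower (median 4.02), with Rpl19 at 34.9 and 1061 TPM and Rpl3 at 89.6 and 827. Immediate early genes, induced by neuronal activity, had 7 of 13 higher and 0 lower (median 1.72), with Arc at 3.10 and 115 TPM and Egr1 at 65.8 and 152. Of 13 GABA-A receptor subunit genes 1 was higher and 10 lower (median -0.38). Gabrd was at 0.80 and 66.4 TPM, and with library totals 4 were lower. Ionotropic glutamate receptor genes had 6 of 14 higher and 5 lower (median 1.36), with Gria2 at 245 and 193 TPM and Grin1 at 9.43 and 185. Heat shock genes had 3 of 8 higher and 2 lower (median 1.23), with Hsp90aa1 at 1341 and 681 TPM. Circadian clock genes had 4 of 10 higher and 2 lower (median 1.35), with Dbp at 5.45 and 61.1 TPM and Nr1d2 at 102 and 61.3. With library totals 7 glutamate receptor and 4 heat shock genes were higher and 0 lower, 6 clock genes were higher and 1 lower, and 10 immediate early genes were higher.

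The neurodegeneration-linked list had 4 of 12 higher and 1 lower (median 1.34), with App at 406 and 884 TPM. Housekeeping genes had 3 of 11 higher and 3 lower (median 1.22), and with library totals 6 and 0. Ywhaz was at 701 and 585 TPM and Ppia at 788 and 2434. Of 9 measured long noncoding RNAs 2 were higher and 5 lower (median 0.07), with Malat1 at 881 and 316 TPM. Proliferation genes had 0 of 6 higher and 1 lower (median 0.26), and adult neurogenesis genes 1 of 6 higher and 2 lower (median 0.38). Among RNAs mostly without a poly(A) tail 1 of 9 was higher (median 0.34), Rn7sk, with 2 and 226 counts (TPM ratio 153, counting interval 41.9 to 1270). Of the 5 sex-linked genes 3 on chromosome Y were lower (median -0.72), with Ddx3y at 53.0 and 26.7 TPM. With library totals 6 neurodegeneration-linked genes were higher and 0 lower, 2 long noncoding RNAs higher and 3 lower, 1 proliferation gene higher and 0 lower, and 1 neurogenesis gene higher and 1 lower. Xist had 2 and 3 counts. Nnt, which lacks exons in C57BL/6J, was at 5.54 and 10.2 TPM.

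Over all list memberships 129 were higher and 87 lower, and adjusted over the list alone the numbers were also 129 and 87. With library totals 158 were higher and 34 lower, and with DESeq2 size factors 128 and 88. On counts, totals in place of TMM raised every list median by about 0.61. The medians of astrocytes, endothelial cells, choroid plexus, proliferation and adult neurogenesis went from negative with TMM to positive with totals. Those of astrocytes were -0.54 and 0.07. No direction is given for these list medians. Count medians of glutamatergic neurons (-0.63 and -0.02), oligodendrocytes (-0.73 and -0.12), cerebellar neurons (-1.04 and -0.43) and long noncoding RNAs (-1.01 and -0.4) were negative with both. Their median log2 ratios of TPM + 1 were above 0 (0.3, 0.26, 0.03 and 0.07), so no direction is given for them either. For blood leukocytes and anterior pituitary the medians, -0.57 and 0.04, are what the scaling gives to equal counts in both libraries, and hold no direction. Relative to the median of all genes, the ribosomal protein list was at 3.14 and the mitochondrial mRNA list at -2.09. Of the 41 lists 31 had a median member at a mean TPM of at least 1. Set against random lists of the same expression, 8 lists lay outside the middle 95%, where chance gives 2.05. Above it were erythroid cells (percentile 99.95), ribosomal proteins (99.69), testis germ cells (99.46), liver (98.8) and RNAs mostly without a poly(A) tail (98.4). Below it were mitochondrial mRNAs (0.0), sex-linked genes (0.07) and GABA-A receptor subunits (0.36). The testis, liver and poly(A)-lacking lists rest on members near 0 counts in replicate 1. Among random lists also matched on GC content, a comparison chosen after seeing the data, the GABA-A (48.04), sex-linked (27.32) and poly(A)-lacking (96.68) lists lay inside the middle 95%. With the length trend removed, the liver (83.89), testis (57.75), GABA-A (3.7) and poly(A)-lacking (44.64) lists lay inside it. The anterior pituitary list, near 0 counts in both libraries, also moved with that correction, to 29.12. Removing the trend thus shifts lists near 0 counts by itself. The moves of the liver, testis and poly(A)-lacking lists therefore decide nothing about length. With CPM scaled by TMM the testis (91.08) and poly(A)-lacking (93.78) lists lay inside, and with members at a mean TPM of at least 1 the liver list (95.47) did. Other lists lay outside under some settings: mural cells with CPM (99.8), with a pseudocount of 0.1 (98.44) and with the length trend removed (99.87), cerebellar neurons with CPM (0.34), microglia with the length trend removed (98.14), and ependymal cells with a pseudocount of 0.1 (98.03). With lists matched on GC content, ependymal cells (99.65) and immediate early genes (0.25) lay outside.

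**Figure D4:**
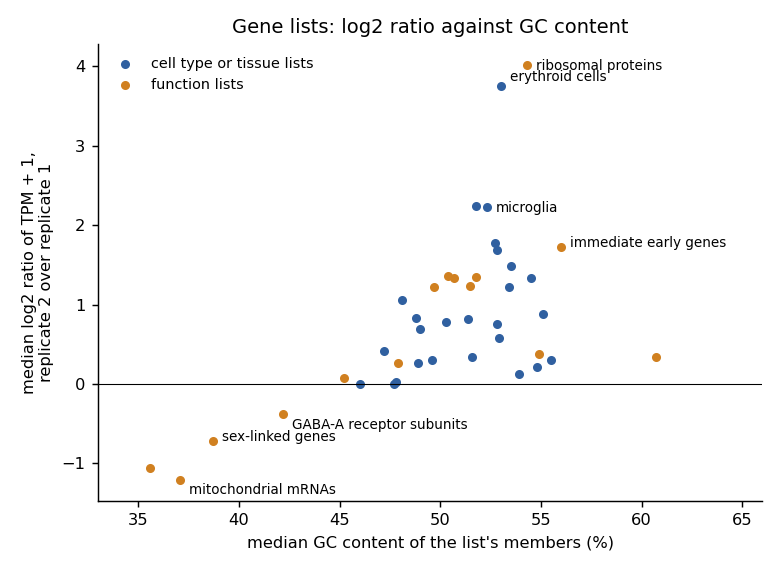
Median log2 ratio of TPM + 1, replicate 2 over replicate 1, of each of the 41 gene lists against the median GC content of its members in percent, with cell type or tissue lists in blue and function lists in orange. Mitochondrial mRNAs lie lowest at -1.21, and ribosomal proteins highest at 4.02.

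The leading transcript, the one holding the largest share of its gene, was the same in both libraries for 4557 of 7437 genes (61.3%, exact binomial interval 60.2 to 62.4%). Of the 28 fixed isoform genes 20 kept it and 8 did not. These 8 were Camk2b, Gad1, Gria1, Gria2, Grin1, Homer1, Mag and Ncam1. For Camk2b, a kinase of synaptic plasticity, ENSMUST00000155755.1 held 61.5% of the gene in replicate 1 and 1.7% in replicate 2, and ENSMUST00000109813.4 held 19.2% and 90.9%. For Gad1, ENSMUST00000140478.1 held 98.7% in replicate 1 and 31.1% in replicate 2. For Ncam1, a neural adhesion molecule, ENSMUST00000114476.3 held 0.0% and 43.8%. The same transcript led in both for Snap25 (99.01% and 94.95%), Mapt (95.4% and 82.4%) and Camk2a (98.6% and 95.4%). Shares of transcripts that overlap are model estimates, and no counting interval was given for them.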

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

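The GC corrections, the median taken about its own value, lists matched on GC content and all settings of the GC trend were chosen after seeing the data, and all other settings before. Pearson's r, 0.666, was 0.804 with no filter on TPM, 0.436 at a mean TPM of at least 10 and 0.914 corrected for a smooth trend on GC content. The median absolute log2 ratio, 0.97, was 1.13 with a pseudocount of 0.1, 0.58 with no filter, 0.68 with posterior mean TPM, 1.13 with CPM scaled by TMM and 0.37 about its median with the GC trend removed. The 9502 differing genes became 3169 with the GC trend removed, 2316 of them also called without it, and under the other settings numbered within a factor of 1.5. The rate of shared leading transcripts, 61.3%, was 63.3% at a gene TPM of at least 20, 59.8% with posterior mean shares and 72.9% where the leading transcript was ahead by 10 percentage points, a construction that leaves out close pairs. The share held by the 100 most abundant genes, 55.0% in the mean, was 31.4% of expected counts and 40.1 to 70.0% with each library left out. The number of lists at a median TPM of at least 1, 31, ranged from 28 to 33 with each library left out. The length trend, -0.24, was -0.29 at a mean TPM of at least 10. Apart from the GC correction, which removes the trend it names, the causes were not tested. The number of lists outside the middle 95% ranged from 6 to 10, and rho with GC content from 0.89 to 0.91. No paired analysis was possible because the libraries are 1 group. Values without a replicate spread counted as moved beyond 10%. Depth limits genes under 10 counts, which were not tested.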

Other observations

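The exon structure values and the GC test of the difference between genes were chosen after the result was seen. Lists matched on GC content were chosen after the GC trend was seen and before their own result, the comparison with random lists after the result, and the other tests before theirs. Exon structure was described within classes of GC content, without a test. Among genes with 55 to 60% GC, 71 genes of 1 exon had a median log2 ratio of 1.51, and 1149 genes with over 4 exon junctions per kilobase had 3.37. At 50 to 55% GC the medians were 0.96 and 1.81, at 45 to 50% 0.33 and 0.44, and at 40 to 45% -0.25 and -0.36, so the classes under 50% hardly differed. Across 13069 protein-coding genes the partial rho with GC content given junctions was 0.9, and with junctions given GC content 0.16. Among the genes of 1 exon, rho with GC content was 0.66. Arf6, a small GTPase gene chosen after its values were seen, has 60.04% GC and was at 28.43 and 21.74 TPM.

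Immediate early and ependymal genes moved when random lists were also matched on GC content. The immediate early list, at percentile 90.97 among lists of the same expression, stood at 0.25 among lists of the same expression and GC content, so its median of 1.72 lay below theirs. The ependymal list went from 96.35 to 99.65. Without GC matching it stood at 89.54 with CPM scaled by TMM and at 84.25 with the length trend removed.

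Genes differed between the libraries far more than counting allows. Poisson draws gave 5.7% of the median absolute log2 ratio about its median (1.06), which argues against counting error. With the length trend removed, 94.6% of it was left, which argues against gene length alone as the main source. Length and GC content were not removed together, so length as a further source stays open. Removing the length trend moved the share of called genes higher in replicate 2 from 59.2% to 47.6%. That share also depends on the level the ratios are centred at, which the fitted trend takes out too. It was 50.9% with the GC trend removed and 84.7% with library totals, so its move decides nothing about length. GC content of the transcript is a candidate explanation: rho with the log2 ratio was 0.89. With the GC trend removed the median absolute log2 ratio about its median was 0.37. Which library is nearer to the tissue was not tested, and 3169 genes still differed after the correction. No biological explanation of this pattern was tested, since the design has 1 group.

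Cell type and function lists differed between the libraries. A different share of cell types in the tissue of each library stays open: the GC-richer members were higher in replicate 2 than the GC-poorer ones in 20 of 20 cell type lists, but also in 99.2% of random lists of the same sizes, so this test decides nothing. GC content as the cause also stays open. Of the 8 lists outside the middle 95%, 5 (62.5%) stayed outside with lists matched on GC content. That share passes the bound of over 50% set before that test as an outcome against GC content. Its exact interval (24.5 to 91.5%) spans 50%, but the use of the interval was added after the share was seen. The interval also treats the lists as independent, and with 8 lists the share is too uncertain to decide. Of the 5 lists, mitochondrial mRNAs (0.02) had a median mean TPM of 7884, and how near in level their matches lay was not examined. The liver (98.93) and testis (98.65) lists rest on members near 0 counts in replicate 1, with a median TPM of 0.77 and 0.525 in replicate 2. The erythroid list (99.89) had a median TPM of 0.38 in replicate 1 and 121.0 in replicate 2. The ribosomal list (99.4) had 40.99 and 564.0. For the GABA-A (0.36 to 48.04) and sex-linked (0.07 to 27.32) lists, which moved inside, GC content may account for their place, while the poly(A)-lacking list, with a median of 0.34 against 0.0 and 0.06 in the lists it was matched to, moved little (98.4 to 96.68).

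The leading transcript differed between the libraries in 2880 genes. In 81.2% of the 2787 such genes with different GC values, the transcript leading in replicate 2 was the GC-richer one (exact interval 79.7 to 82.7%). That is the direction GC content of the transcript would give. The GC content of the leading transcripts, 2 minus 1, differed by a median of 1.6 percentage points. Whether a difference of that size is enough for the switches was not tested. Transcript shares too close to rank cannot be told apart from GC content as a further source. Of the switching genes, 39.6% had leading transcripts within 10 percentage points in share, between the bounds set beforehand. Both may contribute.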
